A study of Mus musculus with 2 samples.

How the data were processed

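H3K4me3 ChIP-seq was carried out by the submitters on forebrain pooled from mouse embryos at embryonic day 16.5 (strain B6NCrl, both sexes), with 2 biological replicates. Per the labels, replicate 2 was a pool of 41 embryos; the number of embryos in replicate 1 is not given in the sources used here. Samples were assigned to the single group from the description in the labels, and replicate numbers were taken from the same text.

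The deposited files are 4 peak lists in narrowPeak format on mm10, with text files that describe how they are related. Per these deposited text files, each replicate's list was derived from its own filtered alignment, that of replicate 1 with 2 further files and that of replicate 2 with 1 further file, whose content they do not give. The pooled list was derived from both replicates' filtered alignments together, and the replicated list from the pooled list and both replicates' lists. The peak caller, the aligner, their versions, the control and the thresholds are not given in the sources used here. In each deposited list the signal value was read as a linear enrichment ratio of the peak, from the narrowPeak column order and the range of the values, since the files do not state its unit; the p- and q-values stand as −log10, the score is an integer that follows −log10 p scaled to the list's maximum, and a summit offset is given in bp. The lowest −log10 p was between 2.00 and 2.09 in the 4 lists, so that weak peaks are included: 98.9% of replicated peaks had a q under 0.05, and 85.9% had a −log10 q of at least 5. The deposited files hold no read counts or coverage, so depth is unknown and no difference in signal between lists was computed: a signal value, score or −log10 p also moves with depth and background, and was used only to rank, filter or describe peaks within a list. A peak's width depends on the caller and on depth as well, so widths are given for each replicate.

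Gene positions came from GENCODE mouse release M21 on GRCm38 (mm10), the build of the files, and sequence from the reference genome of that build. Gene comparisons used chromosomes 1 to 19, X and Y. The 21938 protein-coding entries were collapsed by symbol to 21911 genes (27 symbols had more than 1 entry), with 93513 start sites. A gene was marked where a peak overlapped the window of 1000 bp either side of any of its start sites by at least 1 bp. Domains were made by joining peaks across gaps of up to 1000 bp, and a gene's width is that of the widest domain at its start sites; where genes share a domain, each was given its width. The widest 5% of marked genes were called broad. Peaks away from promoters are those over 1000 bp from every start site of any gene type. Coordinates are given from 1.

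Replicates were compared by overlap of at least 1 bp, against 100 placements of the same peaks at random within their chromosomes, which ignore gaps and mappability. Shares carry Wilson 95% intervals. For 22 gene lists the marked share was tested with Fisher's exact test against all other protein-coding genes, domain width with a permutation test of the median log2 width against 100000 random lists of other marked genes (lists with at least 5 marked members), and broad domains with Fisher's exact test against other marked genes. All tests were two-sided and adjusted by the Benjamini-Hochberg method over the lists, with a threshold of 0.05. The lists cover cortical progenitors, cortical projection neurons, ventral telencephalon and GABAergic neurons, pan-neuronal and synaptic genes, astrocytes, the oligodendrocyte lineage, choroid plexus, midbrain and hindbrain, Hox clusters, endothelial cells, microglia and macrophages, mesenchymal and mural cells, erythroid cells, liver, muscle, germline, cell cycle, immediate early genes, housekeeping genes, olfactory receptors, vomeronasal receptors and clustered protocadherins. All members were found in the annotation. The protocadherin list was made by symbol and held alpha, beta, gamma A and gamma B members, but not those of gamma C. No test compared groups, since there was 1 group.

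The gene lists, the comparisons, the rule for named genes and the alternatives, other than the 2 named below as added, were fixed before the data were examined. From each list the rule for named genes takes the 2 members with the widest domains, the marked member with the highest signal value and the first unmarked member in list order, and all marked or unmarked members where these are 5 or fewer. It adds the 15 genes with the widest domains, the 5 with the highest signal value, the 3 widest domains away from promoters, and the 3 promoter peaks of highest signal value specific to each replicate, with ties broken by symbol. Peaks of equal signal value specific to replicate 2 are all named, a departure made after their values were seen, and genes that share a domain are named together.

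Alternatives were the overlap rule, stricter −log10 q thresholds of 5 and 10, the upper 50% of peaks by signal value, windows of 500 and 2500 bp, the outermost start site, the pooled list, each replicate's own list, joining gaps of 500 and 3000 bp or none, other limits for broad domains, a background without receptor genes, and 10000 random lists matched on the deciles of the CpG observed/expected ratio within 500 bp of the start sites (100000 for width). Added after the data were seen were 2 alternatives: replicated peaks present in both replicates, and each domain counted once. The width test was tested on simulated data: of random lists of 20 among the 14304 marked genes, 5.5% had an unadjusted p under 0.05. Of such lists widened 1.5-fold, 95% had an unadjusted p under 0.05. These shares hold for lists of 20 and the unadjusted p, and not for smaller lists or adjusted calls. Overlap counts were checked against bedtools 2.31.1. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Peaks on scaffolds outside the assembled chromosomes were left out of gene comparisons.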

Results

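Trimethylation of lysine 4 of histone H3 (H3K4me3), a histone mark found at the promoters of active and poised genes, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in the forebrain of mouse embryos at embryonic day 16.5. The tissue came from the strain B6NCrl and was pooled over embryos of both sexes. The series has 1 group with 2 biological replicates, each a separate pool, and replicate 2 held 41 embryos. The design therefore has no contrast between conditions, and the questions it allows are how well the replicates match and where in the genome the mark lies. The data are 4 peak lists on mm10: 1 from each replicate, 1 from both replicates' alignments together (the pooled list), and 1 that keeps part of the pooled list (the replicated list). The files give peaks and no read counts, so the depth is unknown. The signal value of a peak, as the authors deposited it, was read as a linear enrichment, which the files do not state, and was used here only to describe and rank peaks within a list. Tests over genes describe these pooled libraries, because genes are not replicates. They treat each gene as separate, so the p can be too small where members of a list are neighbours, as in gene clusters.

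The mark fell in largely the same places in both replicates. Replicate 1 had 28913 peaks over 35.0 Mb and replicate 2 had 25205 peaks over 31.3 Mb, a mean of 27059 ± 2622 peaks (SD, n = 2). Of the peaks of replicate 2, 96.8% overlapped a peak of replicate 1 by 1 bp or more (95% Wilson interval 96.6 to 97.0), and of the peaks of replicate 1, 80.0% overlapped a peak of replicate 2 (79.5 to 80.4). The same peaks placed at random within their chromosomes overlapped at 2.56% and 2.27% on average, and in none of the 100 placements above 2.76% and 2.43%. The intervals cover counting error only. The peaks without a partner were weak: in replicate 1, none of them lay in the stronger 50% of the list by p, and 30.7% of the 7229 peaks with the weakest p were shared. In replicate 2, 87.3% of the 6302 peaks with the weakest p were shared. Between the 12597 strongest peaks by p of each replicate, which leave out the weak peaks of both, the shares were 97.3% for replicate 1 and 98.4% for replicate 2. Signal values at the 22414 replicated peaks with a peak in both replicates had a Spearman rho of 0.929 across peaks. Peaks are not independent replicates, and no p-value was taken from them.

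**Figure D1:**
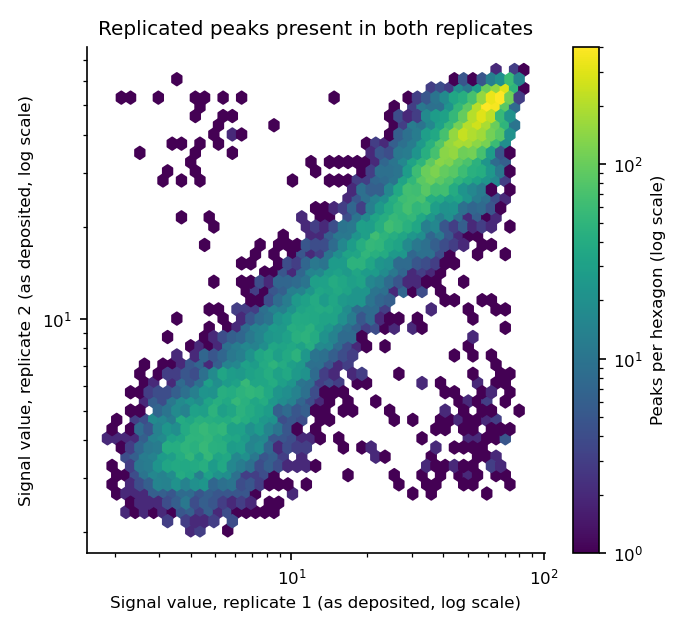
Signal value (as deposited, log scales) of replicate 1 on the x axis and replicate 2 on the y axis at the 22414 replicated peaks that have a peak in both replicates, with the colour giving the number of peaks per hexagon on a log scale. The peaks lie along 1 diagonal band (Spearman rho 0.929), with a small number far from it on either side.

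The replicated list held 25019 of the 26573 pooled peaks and covered 34.5 Mb, with a median peak width of 1182 bp. Of its peaks, 22414 (89.6%) overlapped a peak in both replicates by 1 bp or more. The other 2605 (10.4%) did not: 2115 overlapped a peak of replicate 1 only, 284 a peak of replicate 2 only, and 206 neither. With an overlap of 50% of either peak, every pooled peak present in both replicates was in the replicated list, and 2645 peaks of the list did not meet that rule. The 1554 pooled peaks outside the list were narrow and weak, with a median width of 205 bp and a median signal value of 2.99, against 1182 bp and 24.7 for the replicated peaks.

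Promoters held most of the mark. Of the replicated peaks on the assembled chromosomes, 62.3% lay within 1 kb of a start site of a protein-coding gene, against 6.08% of the same peaks placed at random (highest of 100 placements, 6.37%). The replicates' own lists gave 57.2% and 63.3%, a mean of 60.2% ± 4.36 (SD, n = 2). Among the upper 50% of peaks by signal value the share was 92.1%. Promoter peaks were wider and stronger than the peaks away from every annotated start site of any gene type, with a median width of 1672 bp against 464.5 bp and a median signal value of 43.9 against 5.39. These peaks away from start sites numbered 8074 (32.3%; 37.4% in replicate 1, 31.3% in replicate 2, mean 34.4% ± 4.29, SD, n = 2). They fell to 20.3% of peaks at a −log10 q of at least 10. Of them, 57.3% lay inside gene bodies, against 44.9% by random placement, and 2062 (25.5%) belonged to a joined domain that reached a start site.

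The widest domain away from start sites, 13437 bp at chromosome 15:85669070–85682506, was in an intron of the long noncoding RNA gene Lncppara, 15454 bp from the nearest annotated start site, and measured 14593 ± 2145 bp in the replicates (SD, n = 2). The next, 8821 bp at chromosome 2:115852314–115861134, overlapped no annotated gene. It lay past the 3' end of Meis2, a homeobox gene on the minus strand, and 7733 bp from the nearest start site, an internal one of that gene. The promoter domain of Meis2 is far from it, at chromosome 2:116049600–116076488. This domain past the 3' end measured 4285 bp in replicate 1 and 8572 bp in replicate 2. The last, 7361 bp at chromosome 1:77501570–77508930, lay inside Epha4, which encodes a receptor for ephrins, and overlapped at least 1 of its exons; it measured 7624 ± 1475 bp (SD, n = 2).

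Of 21911 protein-coding genes, 14304 (65.3%) had a replicated peak within 1 kb of a start site and are called marked below. Replicate 1 marked 14400 genes and replicate 2 marked 14220, a mean of 65.3% ± 0.581 (SD, n = 2). A total of 14196 genes were marked in both replicates' own lists, 204 in replicate 1 alone and 24 in replicate 2 alone. Of the 14304 genes, 112 were not marked in both. The promoter peak of highest signal value sat at Cnot8, a subunit of the CCR4-NOT deadenylase complex (signal value 83.9), then Clk1, a kinase that acts on splicing factors (80.6), Hmgcs1, an enzyme of cholesterol synthesis (80.4), and Chmp2b and Pcf11 (both 80.1). On the X chromosome 51.4% of genes were marked, and on the Y chromosome 4 of 183.

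Every member of the 4 lists of forebrain cell types and neurons was marked in both replicates. These are 20 of 20 cortical progenitor genes (Foxg1, Lhx2 and Hes5 among them, the last in a domain shared with Pank4), 20 of 20 genes of cortical projection neurons (Pou3f3, Bcl11b and Cux1), 23 of 23 genes of the ventral telencephalon and GABAergic neurons (Meis2, Dlx1 and Foxp2), and 20 of 20 pan-neuronal and synaptic genes (Tubb3, Gria2 and Ncam1). Cell cycle genes (14 of 14), immediate early genes (12 of 12) and housekeeping genes (17 of 17) were also marked throughout. In each of these 7 lists the share was higher than the roughly 65.3% of other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 22 lists, p from 0.000436 to 0.0206). Against random lists matched on the CpG observed/expected ratio of the promoters, the pan-neuronal share was higher too, with an average of 81.6% marked in the matched lists (adjusted p = 0.0132, permutation test). For the other 6 lists the matched lists averaged 88.0% to 97.8% marked. Since all members of these 6 lists were marked, no higher share was possible and even the highest share did not pass after adjustment, so this test leaves open whether they are marked more often than genes of like CpG content (adjusted p from 0.0990 to 1, permutation test). The ventral telencephalon call was also lost among the upper 50% of peaks by signal value, where the difference from other genes was 9.51 points against 34.8 (adjusted p = 0.407, Fisher's exact test).

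Lists of glial and other brain regions were marked in part, and none of their shares passed the threshold against other genes. How small a difference lists of 12 to 14 genes could show was not measured, so differences stay open. Of 12 astrocyte genes, 9 were marked, and Gfap, Aqp4 and S100b, which are products of mature astrocytes, were not. Of 14 oligodendrocyte lineage genes, 10 were marked in the replicated list and 9 in each replicate's own list. Among the marked genes were Olig2 and Pdgfra, which are expressed in precursors, and Cnp, a myelin gene that had the highest signal value of the list (41.7). The myelin genes Plp1, Mog, Mag and Mobp were not. Of 12 choroid plexus genes, 7 were marked, with Otx2, Cldn3 and Kl among them, and Ttr, Folr1, Kcne2, Aqp1 and Kcnj13 were not. Of 14 midbrain and hindbrain regional genes, 11 were marked, En2 and Atoh1 with the widest domains, and Phox2b, Pax7 and Th were not. The adjusted p of these 4 lists lay between 0.556 and 0.820 (Fisher's exact test). Among the upper 50% of peaks by signal value, the oligodendrocyte, choroid plexus and midbrain and hindbrain lists lay below other genes (adjusted p = 0.00306, 0.00896 and 4.07e-05, Fisher's exact test).

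Markers of non-neural cells that the dissected tissue could hold ranged from partly marked to unmarked. None of 15 microglia and macrophage genes, Aif1 among them, was marked in the replicated list or in either replicate's list (adjusted p = 9.33e-07, Fisher's exact test). Of 12 erythroid genes, 4 were marked (Tal1, Epor, Gypa and Klf1; adjusted p = 0.0443, Fisher's exact test), and none of the other 8, Gata1 among them, was. Of 12 endothelial genes, 7 were marked, including Kdr and Egfl7, whose domain is shared with Gm20532, while Pecam1, Cdh5, Tek, Tie1 and Emcn were not; Pecam1 and Emcn had peaks of 223 bp and 189 bp in replicate 1 alone. Of 13 mesenchymal, meningeal and mural genes, 8 were marked, including Foxc1, Kcnj8 and Twist1, and Col3a1, Dcn, Lum, Rgs5 and Acta2 were not. The endothelial and mesenchymal shares did not pass the threshold against other genes (adjusted p = 0.820 for both, Fisher's exact test). Among the upper 50% of peaks by signal value both lay below other genes (adjusted p = 0.00896 and 0.000959, Fisher's exact test). Against CpG-matched lists the erythroid call was lost (adjusted p = 0.569, permutation test), and the share lay 8.45 points above the matched lists rather than below. For the microglia list that test leaves the question open, since even 0%, the lowest share possible, did not pass against matched lists that averaged 15.5% marked (adjusted p = 0.231, permutation test). The erythroid call was also lost with only the outermost start site of each gene (adjusted p = 0.103, Fisher's exact test), although the difference from other genes was of similar size, −28.3 points against −32.0.

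Genes of other organs, germline genes and chemoreceptor genes were marked less often than other genes. Of 12 liver genes, 2 were marked (Foxa1 and Foxa2, pioneer transcription factors), of 13 cardiac and skeletal muscle genes 4 (Myod1, Ckm, Tnni3 and Gata4), and of 12 germline genes 2 (Gdf9 and Dazl). Albumin (Alb), Myh6 and Ddx4 were not marked, nor were the receptor genes Olfr1 and Vmn1r1. The adjusted p was 0.00192, 0.0266 and 0.00192 (Fisher's exact test). The median signal value of all marked genes was 49.7. The value was 3.19 at Foxa2, 4.58 at Gata4, 6.59 at Myod1 and 6.61 at Tnni3. At Foxa1, Ckm, Dazl and Gdf9 the value was 18.9, 29.1, 29.5 and 57.9. Of 1134 olfactory receptor genes 3 were marked (Olfr94, Olfr658 and Olfr1033), and of 326 vomeronasal receptor genes 1 (Vmn1r4; adjusted p = 1.13e-148, Fisher's exact test). The p of the olfactory receptors was too small for the software to represent. The peaks at Vmn1r4, Ckm and Gdf9 also covered the promoter of a neighbouring gene (Nt5c3, Klc3 and Uqcrq). Against CpG-matched lists the germline and olfactory receptor calls held (both adjusted p = 0.000733, permutation test; matched lists averaged 71.9% and 5.33% marked). Those of the liver (adjusted p = 0.123), muscle (0.656) and vomeronasal lists (0.0559) did not (permutation test). Their shares were 16.7%, 30.8% and 0.307%, still below matched averages of 37.9%, 40.1% and 2.14%. The muscle call was also lost with a window of 2500 bp, with a difference from other genes of −12.5 points against −34.5 (adjusted p = 0.526, Fisher's exact test).

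The Hox clusters stood apart from other CpG-rich promoters. Hox genes encode homeodomain proteins that pattern the trunk and hindbrain and are silent in the forebrain in textbook accounts. Of 39 members, 18 were marked (46.2%; 19 in replicate 1, 14 in replicate 2, mean 42.3% ± 9.07, SD, n = 2), with an adjusted p of 0.0272 (Fisher's exact test). CpG-matched random lists averaged 92.8% marked (adjusted p = 0.000733, permutation test). Both tests count each Hox gene separately, although they lie in clusters and some share a peak (Hoxc5 with Hoxc10, Hoxd3 with Hoxd4). The matched lists were drawn from all other genes, so these p-values can be too small. The widest marked members were Hoxd8 (1166 bp) and Hoxd1 (1095 bp), and Hoxa2 was not marked. The difference of Hox cluster genes from other genes was −19.2 points. With a window of 2500 bp it was −12.5 points and no longer passed (adjusted p = 0.197, Fisher's exact test). It was −29.1 points without replicate 1, −31.3 and −40.8 at a −log10 q of at least 5 and 10, −31.5 for replicated peaks present in both replicates, and −50.7 in the upper 50% of peaks by signal value (adjusted p at most 0.000793, Fisher's exact test). Without replicate 2 it was −17.0 points, and with the outermost start site −18.1 (adjusted p = 0.0423 and 0.0481, Fisher's exact test). Of 53 clustered protocadherin genes, which encode neuronal adhesion molecules, 35 were marked (39 in replicate 1, 28 in replicate 2), a share that did not differ from other genes in the replicated list (adjusted p = 1, Fisher's exact test). At a −log10 q of at least 10 it was lower, with a difference from other genes of −35.5 points (adjusted p = 1.23e-06, Fisher's exact test). The share also differed at a −log10 q of at least 5, in the upper 50% of peaks by signal value and for replicated peaks present in both replicates.

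**Figure D2:**
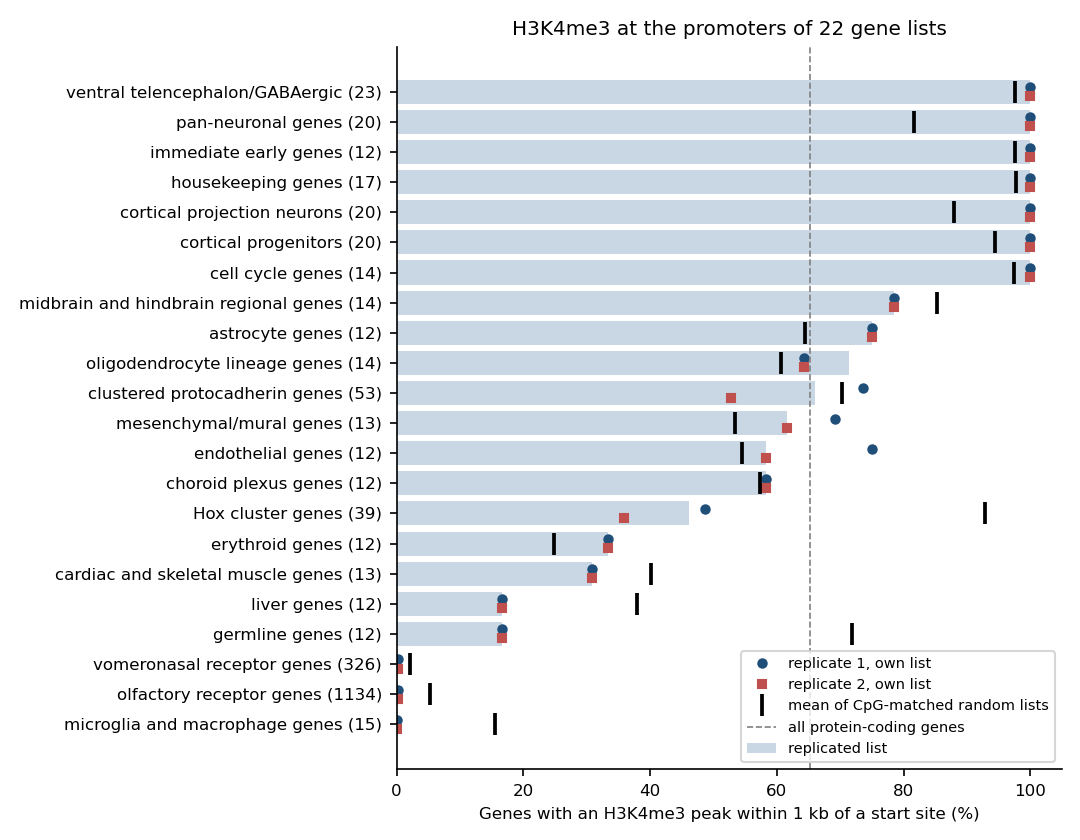
Share of each list's genes (%, x axis) with an H3K4me3 peak within 1 kb of a start site, for 22 gene lists with their number of members in parentheses: bars show the replicated list, blue circles and red squares each replicate's own list, black ticks the mean of CpG-matched random lists, and the dashed line all protein-coding genes (65.3%). Hox cluster genes (46.2%) and germline genes (16.7%) lie far below their matched lists (92.8% and 71.9%).

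Among the 15 lists tested for width, promoter domains, made by joining peaks across gaps of up to 1 kb, were widest in 3 forebrain lists and the pan-neuronal list. The median domain of a marked gene was 1945 bp wide (quartiles 1436 and 2676 bp). Genes of the ventral telencephalon and GABAergic neurons had a median of 9420 bp, 4.85 times that of other marked genes. Genes of cortical projection neurons had 7378 bp (3.80 times), cortical progenitor genes 5266 bp (2.71 times) and pan-neuronal genes 4196 bp (2.16 times). In the replicates' own lists these medians were 8485 ± 1339, 7096 ± 813, 5223 ± 384 and 4074 ± 177 bp (SD, n = 2). For each of these 4 lists no random list was as far from other marked genes (permutation test, two-sided, 100000 random lists; p = 1e-05, the smallest they can give; adjusted p = 2.5e-05 over the 15 lists with at least 5 marked members).

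Immediate early genes (3926 bp; adjusted p = 0.000214, permutation test), housekeeping genes (2965 bp; 0.00538) and cell cycle genes (2920 bp; 0.0101) were wider too, with log2 ratios to other marked genes of 1.01, 0.61 and 0.59. Ccnd2 (7327 bp) and Ccnd1 (6238 bp), cyclins of the G1 phase, led the cell cycle list, Ier2 (6126 bp) and Jun (5259 bp) the immediate early list, and Ywhaz (4711 bp) and Actb (3920 bp) the housekeeping list. The highest signal values of the first 2 of these lists were at Aurka (72.8), in a domain shared with Cstf1, and Dusp1 (58.2), in a domain that also reaches a start site of Ergic1. Astrocyte genes had a median of 3184 bp (1.64 times, adjusted p = 0.0156, permutation test), led by Nfia, in a domain shared with E130114P18Rik (9685 bp; 14432 bp in replicate 1 and 5943 bp in replicate 2) and Sox9 (6930 bp), which also belongs to the progenitor list. Without joining, the calls for astrocyte (adjusted p = 0.403), cell cycle (0.0501) and housekeeping genes (0.0685) were lost (permutation test). The astrocyte call was also lost without replicate 1 (adjusted p = 0.153, permutation test).

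Hox genes had narrow domains, with a median of 744 bp (0.383 times that of other marked genes; 696 ± 56.8 bp in the replicates, SD, n = 2), and so did clustered protocadherins, with 472 bp (0.243 times; 538 bp in replicate 1 and 471 bp in replicate 2). Both had an adjusted p of 2.5e-05 (permutation test). Pcdhga12 (2410 bp) and Pcdhac2 (2115 bp) were the widest promoters of the protocadherin list, which leaves out gamma C members, and Pcdha1 was not marked. Oligodendrocyte lineage genes had a median of 1182 bp (0.608 times, adjusted p = 0.00937, permutation test), but this call did not hold in either replicate alone: their log2 ratio to other genes was 0.13 in replicate 1 and −0.44 in replicate 2 (adjusted p = 0.786 and 0.152, permutation test). The choroid plexus, midbrain and hindbrain, endothelial and mesenchymal lists had medians from 1651 to 2067 bp. They did not pass the threshold against other marked genes (adjusted p from 0.424 to 0.877, permutation test). Without joining, the midbrain and hindbrain list was narrower (adjusted p = 0.0105, permutation test).

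**Figure D3:**
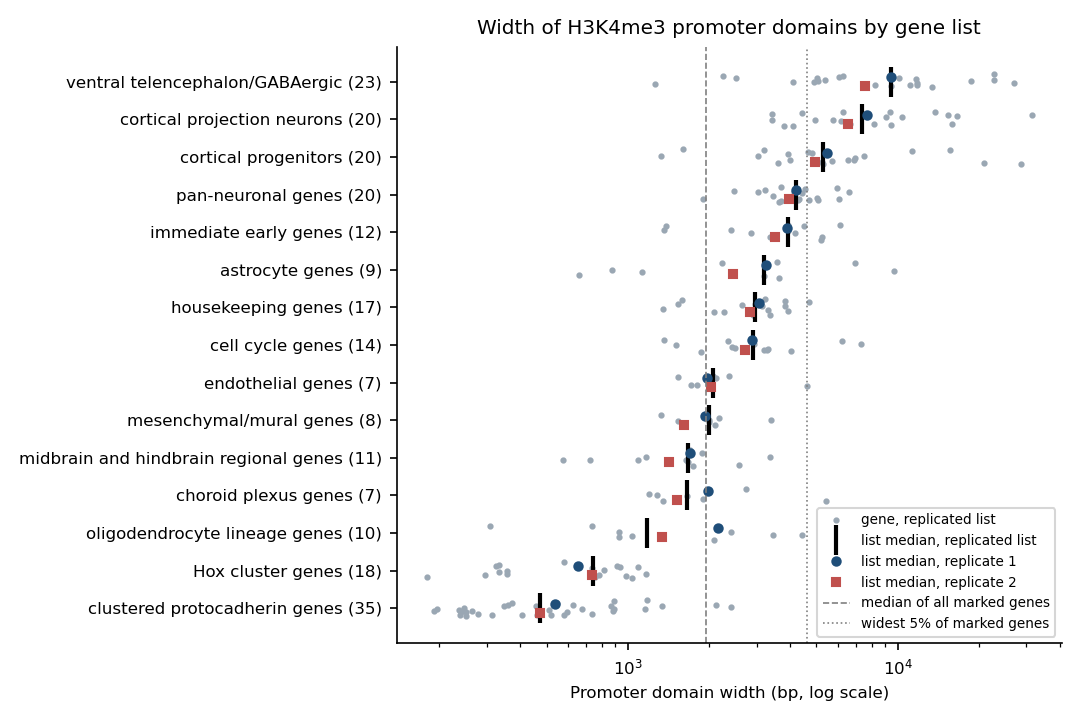
Width of H3K4me3 promoter domains (bp, log scale, x axis) for the 15 gene lists with at least 5 marked members, whose number is in parentheses: grey points are genes and black ticks list medians in the replicated list, and blue circles and red squares are list medians in replicates 1 and 2. The dashed line is the median of all marked genes (1945 bp) and the dotted line the limit of the widest 5% (4609 bp); the medians of 3 forebrain lists lie above the latter in the replicated list.

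Of the 15 genes with the widest domains, 9 belong to the forebrain lists. The first was Pou3f3, a POU-domain factor, with 31381 bp on chromosome 1:42683290–42714670, which covered the whole gene and measured 31297 ± 32.5 bp in the replicates (SD, n = 2). It was followed by Foxg1, a forkhead factor of the telencephalon, which shares its domain with Gm43517 (28579 bp, chromosome 12:49373691–49402269), Meis2 (26889 bp, chromosome 2:116049600–116076488), Nfib (25386 bp) and Bcl11a with A830031A19Rik (24053 bp). Dlx1 and Dlx2, homeobox genes of the ganglionic eminences, lay whole within 1 domain of 22717 bp (chromosome 2:71524556–71547272; 23042 ± 646 bp in the replicates). Lhx2 (20966 bp), Mn1 (20187 bp), Dlx6 (18630 bp), Nr2f1 (16838 bp), Bcl11b (16637 bp) and Satb2 (15865 bp) completed the 15. Some of these widths varied between replicates: Dlx6 measured 29808 bp in replicate 1 and 18147 bp in replicate 2, Lhx2 21817 and 13126 bp, and Foxg1 28638 and 21711 bp. They also rest on joining, since the widest single peak was 16119 bp at Pou3f3, 5369 bp at Foxg1, 4501 bp at Dlx6 and 4256 bp at Nr2f1.

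**Figure D4:**
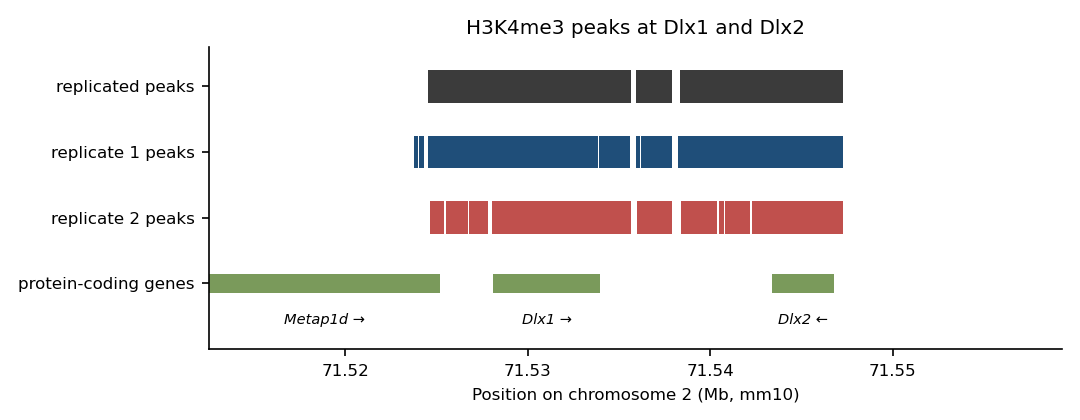
Peaks of the replicated list, replicate 1 and replicate 2 and the protein-coding genes around Dlx1 and Dlx2 on chromosome 2 (x axis, position in Mb, mm10), with arrows giving each gene's strand. The replicated peaks form 1 joined domain of 22717 bp that covers both genes, and both replicates show it.

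The widest 5% of promoter domains (at least 4609 bp) belonged to 716 genes in 645 domains. The forebrain lists and the pan-neuronal list were over-represented among them: 19 of 23 marked ventral telencephalon genes were broad, 15 of 20 genes of cortical projection neurons, 13 of 20 cortical progenitor genes and 6 of 20 pan-neuronal genes, against about 5% of other marked genes. Their adjusted p was 1.7e-20, 2.48e-15, 3.12e-12 and 0.00122 (Fisher's exact test against marked genes, two-sided, 15 lists). No other list passed the threshold, although 3 of 12 immediate early genes were broad (adjusted p = 0.0587, Fisher's exact test). That list passed in 5 alternatives: without joining (0.00773), at a −log10 q of at least 5 and 10 (both 0.00668), for replicated peaks present in both replicates (0.00667), and with the widest 10% called broad (0.000151; Fisher's exact test). With the widest 1% called broad, the pan-neuronal list was no longer over-represented (adjusted p = 1, Fisher's exact test). Of the 716 genes, 654 belonged to none of the 22 lists.

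The peaks found in a single replicate were narrow, weak and mostly away from promoters. On the assembled chromosomes replicate 1 had 5794 such peaks, with a median width of 223 bp against 1278 bp for its shared peaks, a median signal value of 3.40 against 29.1, and 20.7% at promoters against 66.3%. Replicate 2 had 805 (3.20% of its peaks), with a median width of 205 bp against 1101 bp, a median signal value of 3.38, and 20.0% at promoters against 64.7%. With an overlap of 50% of each peak required, 7719 peaks of replicate 1 and 4012 of replicate 2 had no partner. The strongest specific promoter peaks of replicate 1 lay at Kifc3 (signal value 8.53), the histone gene Hist1h3f (7.54), whose domain is shared with Hist1h2bh, and Pnisr (7.21). Those of replicate 2 lay at Gm14325 and Gm2237 (both 5.55), Gm14418 (5.31), and Calb2, Idi1 and Wiz (each 5.07). Kifc3, Hist1h3f, Pnisr, Gm2237, Calb2, Idi1 and Wiz were nonetheless marked in both replicates, and Gm14325 and Gm14418 in replicate 2 alone.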

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

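The tests of peak strength, of peak edges and of other cells in replicate 1, of CpG content around start sites, and of CpG-rich promoters in other tissues were chosen only after the results they bear on had been seen. The alternative without joining was planned, but was weighed as an explanation only once its result had been seen, and the bootstrap intervals were added once the width ratios they bound had been seen. The replicated list held 12 peaks on 6 unplaced or unlocalised scaffolds, with signal values from 2.31 to 50.8. They are listed because no gene comparison used them, and no expected number was at hand to set them against.

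Replicate 1 had 5794 peaks with no partner in replicate 2, and replicate 2 had 805 with none in replicate 1. Edges of shared regions called as separate peaks are not the whole cause, since 49.8% of the specific peaks of replicate 1 lay within 1 kb of a peak of replicate 2, although random placement gave 1.67%. Weak peaks near the calling threshold stay open: 0 of the 5794 (0%) lay in the stronger 50% of the list of replicate 1, but this restates that the peaks without a partner are weak and does not test why replicate 1 has more of them. Cells of another type in the pool of replicate 1 cannot be told apart from chance: of 38 genes of endothelial, microglial, mesenchymal, erythroid and choroid plexus lists without a peak in replicate 2, replicate 1 marked 3 (7.89%, Wilson 95% interval 2.72 to 20.8; Pecam1, Emcn and Dcn), against 2.63% of other genes (p = 0.0788, Fisher's exact test). Depth, the further files used in peak calling and the size of the pools are open and could not be tested, and no biological explanation was tested because both replicates belong to 1 group.

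Promoter domains of the 4 forebrain and neuronal lists were wide. Against genes matched on the number of CpGs within 5 kb of the start sites, at least 66.0% of the log2 width ratio was left in each list, the least in cortical progenitors (from 1.44 to 0.95, 95% bootstrap interval 0.54 to 1.34). Matching on the number of annotated start sites left at least 97.1%. Without joining, at least 56.2% was left, the least in the ventral telencephalon list (from 2.28 to 1.28, 95% bootstrap interval 0.66 to 1.87). The adjusted p was at most 5e-05 in each list under all 3 (permutation test). Start site number alone or joining alone is therefore not the whole cause, although joining may account for part. CpG content may account for part or more. It was matched only by decile and within 5 kb of the start sites, less than the widest domains reach. The 3 were not combined, so their joint effect is open. The hypothesis that wide domains mark the genes that set forebrain identity stays open, and no biological explanation was tested because the design has 1 tissue and 1 age.

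Genes of other tissues and cell types carried the mark: 63 of the 154 members of the choroid plexus, midbrain and hindbrain, Hox, endothelial, microglia, mesenchymal, erythroid, liver, muscle and germline lists. The promoter of a neighbouring gene is not a sufficient cause, since 11.1% (7 of 63, of which 4 are Hox genes paired with each other) shared the marking peak with another protein-coding gene, against 21.4% of other marked genes. CpG-rich promoters remain a candidate explanation. The median CpG ratio was 0.711 in marked and 0.330 in unmarked members (difference 0.381, permutation test, p = 1e-05, the smallest that 100000 permutations can give). Over all these lists CpG content alone does not set the number. Of 154 members 63 were marked, against a mean of 92.4 in CpG-matched lists (central 95% from 85 to 99). Without the Hox and germline lists, 43 of 103 were marked against 47.6, which is inside the matched range (42 to 54). Those lists were left out after their shares had been seen. Other cell types in the dissected tissue stay open: of 43 low-CpG members of the endothelial, microglia, mesenchymal and erythroid lists, 10 (23.3%, Wilson 95% interval 13.2 to 37.7) were marked, against 32.0% of other low-CpG genes (p = 0.254, Fisher's exact test). The 10 were Cldn5, Col1a1, Col1a2, Epor, Erg, Esam, Gypa, Kcnj8, Klf1 and Pdgfrb. No gene in the microglia list was marked, nor were the globin genes of the erythroid list, where mappability was not examined. The share pools all these lists, so the wholly unmarked microglia list can lower it. Klf1 and Gypa were marked in both replicates, with signal values of 30.6 and 37.5 in the replicated list.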

How the results depend on the processing

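Replicated peaks present in both replicates and each domain counted once were alternatives chosen after seeing the data. No paired analysis was possible because the series has 1 group. The cause of the changes below was not tested, except where a threshold or window by its construction leaves fewer peaks or longer promoters. The share of replicate 1 peaks in replicate 2 (80.0%) was 73.3% with 50% of each peak required, 78.7% with 50% of either, 86.5% and 89.8% at a −log10 q of at least 5 and 10, 97.3% between the 12597 strongest peaks of each replicate and 88.1% after joining; that of replicate 2 peaks (96.8%) was 84.1%, 95.7%, 99.0%, 99.7%, 98.4% and 97.9%. With the stricter −log10 q applied to both replicates' lists, 3007 and 1958 peaks of replicate 1 had no partner (5794 in the main setting). For replicate 2 these counts were 204 and 53 (805 in the main setting). They can include peaks whose partner lay below the threshold. With 50% of each peak required, 7719 peaks of replicate 1 and 4012 of replicate 2 had no partner. The share of peaks at promoters (62.3%) was 69.7% with 2500 bp, 69.0% and 74.8% at the stricter −log10 q, 92.1% in the upper 50% by signal value, 51.1% with the outermost start site, 67.2% for replicated peaks present in both replicates, and 57.2% to 63.3% without either replicate. Peaks away from promoters (32.3%) were 25.8% and 20.3% at the stricter −log10 q, 24.0% with 2500 bp, and 31.3% to 37.4% without either replicate.

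The number of marked genes ranged from 12208 (upper 50% by signal value) to 14535 (2500 bp). Of the 15 lists whose marked share differed, 4 passed against CpG-matched lists; of the others, 7 were at 100% or 0%, the limit of the share. The number was 13 to 20 under the other alternatives. The erythroid share turned from below other genes to 8.45 points above its matched lists. The lists that differed in width (11) numbered 9 to 11 and those over-represented among broad domains (4) 3 to 5. The log2 width ratio of oligodendrocyte lineage genes was −0.72 in the replicated list, −0.44 without replicate 1 and 0.13 without replicate 2, and the pan-neuronal broad share was −1.01 points with the widest 1%. The 4 forebrain and neuronal lists kept their wider call under all 11 width alternatives. Of the widths of marked named genes, 28 of 77 moved by over 1.5 times without joining, 9 with a gap of 3 kb, 5 without replicate 1 and 2 of 76 without replicate 2. Depth, which the files do not give, limits the detection of weak peaks.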

Other observations

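All 17 gene families below were chosen after the data were seen, by their symbols, and their tests were adjusted over these families alone. All 16 ionotropic glutamate receptor genes with the symbols Gria, Grin or Grik, which leave out Grid genes, were marked. Their median domain was 3784 bp (adjusted p = 9e-05, permutation test), led by Grin2b, Grik3 and Gria2, the last also in the pan-neuronal list. All 22 ephrin and Eph receptor genes, which guide axons, were marked, with a median of 3313 bp (adjusted p = 9e-05, permutation test), led by Efnb1, Efnb2 and Epha4. Teneurin, contactin and neurexin genes, which encode adhesion proteins of neurons, were marked in 12 of 13 cases with a median of 4710 bp (adjusted p = 7.5e-05, permutation test). Of 20 semaphorin genes 18 were marked, with a median of 2878 bp (adjusted p = 0.00658, permutation test). These 4 families were also wider than CpG-matched genes (adjusted p from 5e-05 to 0.00174). GABA-A receptor genes did not differ in width (14 of 19 marked, median 1945 bp, adjusted p = 1, permutation test); Gabra6, Gabrp, Gabrr1, Gabrr2 and Gabrr3 were unmarked.

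Sox genes, which encode transcription factors, were the widest family tested, with a median of 5964 bp over 18 of 19 marked genes (adjusted p = 7.5e-05, permutation test), led by Sox6 (in a domain shared with 1110004F10Rik), Sox2 and Sox5; Sox15 was unmarked. Forkhead genes (36 of 44 marked, median 2305 bp) and Wnt genes (17 of 19, median 1667 bp) did not pass the threshold in width (adjusted p = 0.108 and 0.255, permutation test). Of 394 zinc finger genes 347 were marked (88.1%), with a median width of 1722 bp, narrower than other marked genes (adjusted p = 9e-05, permutation test) but not than CpG-matched ones (0.488). Ribosomal protein genes were marked in 80 of 83 cases, all but Rpl10l, Rpl39l and Rpl3l, and proteasome subunit genes in 38 of 40, all but Psma8 and Psmb11. Of 53 keratin genes 4 were marked, of 42 beta-defensin genes 0, and of 100 cytochrome P450 genes 25, with a median width of 1259 bp (adjusted p = 0.00055, permutation test; 0.119 against CpG-matched genes). Fgf genes (17 of 22 marked), solute carrier genes (262 of 371) and potassium channel genes (75 of 94) did not differ in width (adjusted p = 0.184, 0.184 and 0.180, permutation test), although the last were wider than CpG-matched genes (0.0099), and ribosomal protein and proteasome genes did not either (0.180 and 0.153). Among 7959 long noncoding RNA genes with a start site over 2 kb from those of protein-coding genes, 818 (10.3%) were marked, and in the replicates 10.9% and 9.65%.

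Of the 8074 replicated peaks away from annotated start sites, 922 (11.4%) lay within 1 kb of a start site of the RefSeq annotation, against at most 2.18% in 100 random placements. Their median CpG ratio was 0.386, between that of peaks at start sites (0.667) and random positions (0.160).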
